A study of Mus musculus with 4 samples.

How the data were processed

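The libraries were single-cell RNA of live CD45+ cells sorted by flow cytometry from mouse fibrosarcomas on day 11, made with 10x Genomics 3′ chemistry. Each group had 2 libraries, and each library was a pool of 2 tumours, so 4 tumours stand behind each group. The library was the replicate, and cells were not counted as replicates. The p-values of single genes and of shares therefore measure the spread between pools of tumours and not that between single tumours or cells. The p-values of gene lists from camera at a preset correlation compare the listed genes with the other genes tested. Their size depends on the number of listed genes and on that preset, and is not a measure of the spread between pools. With 2 libraries against 2, the smallest exact permutation p was 0.333.

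The deposited values were counts of unique molecular identifiers (UMIs) per barcode and gene, as the file headers and whole-number entries showed. Per the submitters' processing notes, reads were handled with Cell Ranger and cells with Seurat 3.1.0 in R 3.6.0, and the builds GRCh38 and mm10 were named. Per the file headers the matrix software was version 3.1.0. Of the 31053 features, 30934 (99.6%) matched a mouse Ensembl identifier of GENCODE vM21, which gave coordinates on GRCm38 (mm10). The lowest UMI count per barcode was 500, 500, 500 and 504 (control 1, control 2, DKO 1, DKO 2), so shallower barcodes were already absent from the deposited files.

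The following choices were made before the data were examined, unless stated. Cells needed at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs. This removed 930, 663, 636 and 570 barcodes, each of them above the mitochondrial limit. Doublets were scored with Scrublet in each library, and the highest scores were removed at 0.8% per 1000 barcodes, which marked 678, 601, 415 and 236 barcodes, some of which had also failed the cell filter. The automatic Scrublet threshold would have marked 129, 126, 114 and 46. Of 30504 barcodes, 27705 passed the cell filter and 25881 of those stayed after doublet removal. Counts were log-normalised, 2000 variable genes were taken, and a graph of 20 neighbours on 30 principal components was clustered with Leiden at resolution 1, without any integration of libraries. No correction for free RNA was applied, as the files held no empty droplets.

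Clusters were named by fixed marker lists compared with their leading genes, and classes are called "like" their namesakes because markers alone name them. A class was tested where each library held at least 50 of its cells. A rule set after the clusters were seen kept a cluster with Cd3e in at least 50% of its cells from being named NK or innate lymphoid. It moved cluster 4 (Klra6, Klra1, Trdc), with Cd3e in 82.6% of cells, to the T class. That cluster made up 36.7% (34.2 to 39.1) and 32.5% (29.8 to 35.4) of the T-like cells in control and 21.5% (19.7 to 23.5) and 30.5% (28.0 to 33.1) in DKO. Cluster 22 (Il13, Il5), with Cd3e in 91.8% of cells, had innate lymphoid as its best name before the Cd3e rule. Under that rule it was left unnamed, as its leading genes held 0 markers of the next best name and 4 of another class. The monocyte/macrophage-like cells were clustered again on their own into 17 clusters, without Dnase1l3 among the variable genes because that gene had been called. Cluster M16 (10, 7, 7 and 6 cells) was led by the T and NK cell genes Gzma, Nkg7 and Cd3d and was left in the class.

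Counts were summed per library and class and fitted with edgeR (TMM factors, filterByExpr, robust quasi-likelihood F test, group as the single factor). The Benjamini-Hochberg adjustment ran over the genes tested in a class, with a threshold of 0.05. Counts of called members of a list were adjusted over the list alone. Shares used the same edgeR test on cell numbers with the library total as offset. The 29 gene lists were written from general knowledge and tested with camera in limma at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. The difference of the change between monocyte/macrophage-like and T-like cells was a class-by-group term in edgeR with the library as block. Genes picked from all those tested in a class had at least 20 CPM in the higher group, apart from Tspan9 and Tnfsf11, which were added after their values were seen. That limit did not apply to the targeted genes, to fixed marker genes, to members named for a gene list or to the class-by-group term. A count of 3 in a library was the floor for calling a transcript present. Intervals in brackets after a single library's share are 95% Clopper-Pearson intervals, and they and the floor cover counting error alone.

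Each test was tested on simulated data with known changes. Simulated genes had the dispersion of the fitted trend, without the spread of single genes around it. Recovery and false calls in the real data can therefore differ from the values below, and few calls do not exclude changes of the simulated sizes. For a log2 change of 1, edgeR recovered 71.6% of genes in all CD45+ cells, 72.2% in monocyte/macrophage-like, 59.6% in dendritic-like, 20.6% in neutrophil-like, 77.8% in T-like and 71.4% in NK-like cells. A log2 change of 2 was recovered for 88.9%, 99.0%, 96.8%, 87.6%, 98.0% and 97.0% of genes. False calls made up 8.77%, 2.91%, 6.25%, 2.00%, 6.95% and 2.92% of calls. DESeq2 recovered 67.0%, 69.0%, 39.0%, 12.0%, 59.0% and 40.0% of the genes with a log2 change of 1. The class-by-group term recovered 52.8% at a log2 difference of 1 and 95.3% at 2. With the preset correlation, camera called the raised list in 5 of 5 classes and 0 unchanged lists. With an estimated correlation it called the raised list in T-like cells alone (adjusted p = 0.0488), and fry called it in monocyte/macrophage-like (0.0135), dendritic-like (0.0429) and T-like cells (0.00331). Members of the simulated lists were drawn without correlation, so these runs cannot show how often the preset calls unchanged lists of correlated genes. In monocyte/macrophage-like cells the estimated correlation was 0.45 for monocyte identity, 0.63 for MHC class II presentation and -0.01 for the retinoic acid response. The share test called a doubled class in 25 of 50 simulations, at a between-library coefficient of variation of 0.15. There were 25 calls among 400 tests of other classes. Their shares fell as the doubled class rose, so this is not a rate of false calls. The real spread was wider in some classes, such as neutrophil-like cells at 3.39 ± 1.83% in control.

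The alternatives were DESeq2 and its size factors, no low-count filter, sums thinned to equal depth, equal cell numbers, a stricter cell filter (500 genes, 1000 UMIs, 5% mitochondrial) or none, no doublet removal, Leiden resolutions of 0.5 and 2.0, limma on log ratios for shares, a denominator without the most numerous class, and leaving out each library. Leaving out a library leaves an arm with 1 library, which is then assumed to vary like the others. Leaving cluster 4 out of the T class was added after the first results. Of the monocyte/macrophage clusters, the 5 with the smallest p were followed through the alternatives, a choice made after the values were seen. The values of some single members of gene lists are not reported here. Velocity, trajectories, receptor-ligand scores and clonotypes were left out, since the files held no spliced counts, time course or receptor sequences.

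Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.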

Results

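To assess how tumour leukocytes differ when tumour cells lack the retinoic acid-making enzymes Raldh1 and Raldh3, single-cell RNA of live CD45+ cells sorted from mouse fibrosarcomas on day 11 was compared between Raldh1/3 double knockout (DKO) and Cas9 control tumours. There were 2 libraries per group, each a pool of 2 tumours. The files held 9206 and 8668 barcodes in control 1 and 2 and 7201 and 5429 in DKO 1 and 2. Depth was 80032966, 74878771, 71381613 and 57458026 UMIs, with a median of 6653, 7194, 6544 and 7581 UMIs per barcode. After filtering, 7642, 7416, 6177 and 4646 cells in 30 clusters were kept. Values below are mean ± SD of 2 libraries, and log2 changes are DKO over control ± standard error.

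To check the targeted genes, transcripts of Aldh1a1 (chr19:20492715-20643465, GRCm38), which encodes Raldh1, and of Aldh1a3 (chr7:66390890-66427517), which encodes Raldh3, were counted in each library. Aldh1a1 had 1 and 0 UMIs in control and 0 and 1 in DKO, below the floor of 3 in all 4 libraries. Aldh1a3 had 28 and 9 UMIs in control and 10 and 23 in DKO (log2 0.04, adjusted p = 0.990). In cluster 27, led by collagen genes and nearest to tumour cells or fibroblasts (33, 17, 24 and 13 cells), Aldh1a3 had 9 and 3 UMIs in control and 0 and 0 in DKO, while Aldh1a1 had 0, 0, 0 and 1. Aldh1a2, which encodes the Raldh2 of myeloid cells, had 72 and 36 UMIs in control and 38 and 126 in DKO (log2 0.82, adjusted p = 0.630; log2 -0.43 without DKO 2). The Aldh1a3 value over all cells was log2 -0.50 without control 2 and -0.80 without DKO 2. Dhrs3, a retinoic acid-induced retinaldehyde reductase, was at 141 ± 8.25 CPM in control and 108 ± 5.19 in DKO (log2 -0.38, adjusted p = 0.296), but in cluster 27 it was at 18.9 and 24.0 CPM in control and 42.5 and 38.2 in DKO (34, 19, 62 and 36 UMIs). Rarb had 3, 4, 2 and 5 UMIs and Cyp26b1, which encodes a retinoic acid hydroxylase, had 1, 4, 3 and 29. These 3′ tags check the knockout little, since guide positions are not given and the CD45+ sort removed most tumour cells.

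To assess the makeup of the CD45+ sort, cells were assigned to 10 classes. Monocyte/macrophage-like cells made up 68.4 ± 2.54% of the sorted cells in control and 53.5 ± 1.58% in DKO (log2 -0.36 ± 0.15, adjusted p = 0.144). T-like cells were at 17.3 ± 3.61% and 28.3 ± 1.06% (log2 0.71 ± 0.22, adjusted p = 0.144), and NK-like cells at 5.01 ± 0.463% and 7.31 ± 0.770% (log2 0.54, adjusted p = 0.144). Within the T class the most cells lay in cluster 4 (Klra6, Klra1, Trdc) in control (34.6%), while in DKO clusters 7 (Cd8a, Gzmk) and 4 held 26.2% and 26.0%, with cluster 7 ahead in DKO 1 and cluster 4 ahead in DKO 2. Within the monocyte/macrophage class they lay in cluster 0 (Cd163, Pf4) in control (22.5%, ahead in control 2, with cluster 1 ahead in control 1) and in cluster 2 (Igf1, Apol7c, Dnase1l3) in DKO (24.9%). The log2 value was 0.32 for dendritic-like cells (0.54 without control 1, 0.13 without control 2, 0.55 without DKO 1 and 0.05 without DKO 2). It was -0.45 for neutrophil-like cells (0.24 without control 2) and 0.78 for B-like cells (0.50 without DKO 2). Plasmacytoid dendritic-like cells were at 0.39 (-0.09 without control 2, -0.38 without DKO 2). Mast or basophil-like cells were at 2.37 (0.59 without DKO 2, and 3.17 at the highest without 1 library), and tumour or fibroblast-like cells at -0.41.

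Of the 10 classes, 7 had no overlap between groups (33.3% would by chance), and an exact permutation test gave each of these p = 0.333, the smallest it can give. By the edgeR quasi-likelihood test 0 of 10 shares changed (Benjamini-Hochberg, smallest adjusted p = 0.144; exact permutation p at least 0.333), 2 had an unadjusted p below 0.05 (T-like, p = 0.0433, and the unnamed cluster, p = 0.0338), and limma on log ratios called 0. Without DKO 1, 2 classes passed, mast or basophil-like cells among them (adjusted p = 0.0307). As shares are bound to each other, the fall of one raises the rest: with the most numerous class left out of the denominator the NK-like value was log2 -0.03 and the dendritic-like value -0.24. T-like cells numbered 1517, 1094, 1796 and 1281 beside 5092, 5208, 3373 and 2433 monocyte/macrophage-like cells (control 1, control 2, DKO 1, DKO 2). The rise of the T-like share therefore cannot be told apart from the lower monocyte/macrophage-like share.

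**Figure D1:**
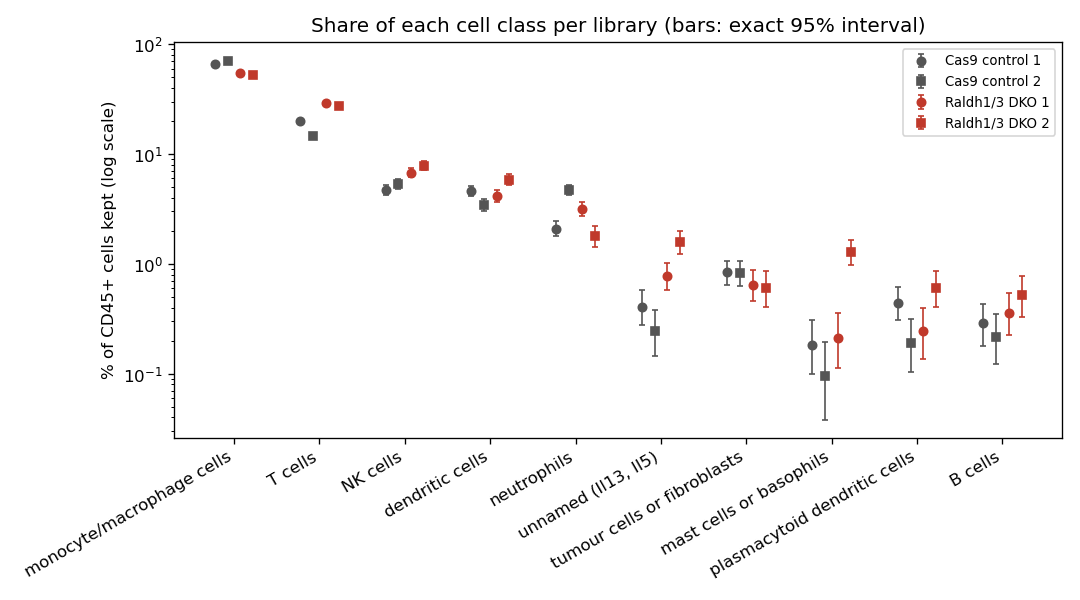
Share of each cell class among the sorted CD45+ cells in each of the 4 libraries.

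To assess transcripts over all CD45+ cells, which also move with the makeup of the sample, counts were summed over every cell kept. Genes with the smallest adjusted p (0.154) were Apol7c (log2 2.16), Dnase1l3 (1.55), Zap70 (1.05), which encodes a kinase of T cell receptor signalling, Pid1 (-1.12), Clec12a (-0.82), an inhibitory myeloid receptor, and Susd3 (-0.80). Irf4, which encodes a transcription factor of activated T cells and dendritic cells, was at log2 1.15 ± 0.24 (adjusted p = 0.229). With edgeR, 0 of 14427 genes changed, while 1797 had an unadjusted p below 0.05 and DESeq2 called 407. Without control 1 edgeR called 22 genes. Groups did not overlap for 46.9% of genes (33.3% by chance).

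To assess the monocyte/macrophage-like cells, the class whose differentiation the series asks about, 13011 genes were tested. Dnase1l3 (chr14:7964533-7994573), which encodes a secreted nuclease of macrophages and dendritic cells, rose from 24.2 ± 0.299 to 83.5 ± 7.58 CPM (log2 1.78 ± 0.12, adjusted p = 0.0374). Its adjusted p was 0.0513 without DKO 1, 0.0643 without DKO 2 and 0.0724 with a stricter cell filter. As a leading gene of cluster 2, Dnase1l3 also moves with the mix of clusters in the class. That cluster held 13.6% and 5.09% of the class in control and 23.1% and 26.8% in DKO. The change of Dnase1l3 at an equal mix of clusters was not tested. Without a call, Apol7c, which encodes an apolipoprotein L of antigen-presenting cells, was at log2 2.67, the chemotaxis-linked Susd3 at -1.02, Pid1, which encodes an inhibitor of insulin signalling, at -0.93 and the formin gene Inf2 at -0.93. Irf4 was at log2 0.70 (-0.09 without DKO 2) and Aldh1a2 at 1.15 (-0.31 without DKO 2). The edgeR quasi-likelihood test called 1 gene and DESeq2 136, with 1077 at an unadjusted p below 0.05. Leaving out control 1, control 2, DKO 1 or DKO 2 gave 243, 25, 1 and 0 calls. Groups did not overlap for 40.2% of genes (33.3% by chance).

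Genes of monocyte identity were lower in DKO monocyte/macrophage-like cells: S100a4, a calcium-binding protein of motile monocytes, was at 741 CPM in control and 380 in DKO (log2 -0.96), Ifitm6 at log2 -0.98 and the acute-phase gene Hp at -1.62. The list fell (camera adjusted p = 2.10e-09, median log2 -0.41, 19 of 20 members negative, 1 called when adjusted over the list alone, and adjusted p = 0.729 with an estimated correlation). From mean CPM the median of monocyte identity was log2 -0.38. It was -0.58 without control 1, -0.15 without control 2, -0.35 without DKO 1 and -0.61 without DKO 2. Genes of MHC class II presentation were higher, with H2-Aa at 2300 and 3397 CPM (log2 0.56), the peptide editor gene H2-DMb2 at 0.86 and H2-Oa at 0.82. That list rose (camera adjusted p = 5.95e-07, median log2 0.46, 11 of 11 positive, and adjusted p = 0.729 with an estimated correlation). From mean CPM the median of MHC class II presentation was log2 0.49. It was 0.70 without control 1, 0.30 without control 2, 0.70 without DKO 1 and 0.24 without DKO 2. The interferon gamma response list rose (adjusted p = 2.29e-06, median 0.32, 20 of 21 positive; adjusted p = 0.729 with an estimated correlation), with the GTPase genes Irgm1 at 0.50 and Gbp3 at 0.39, but had adjusted p = 0.356 without control 1 and 0.0574 without DKO 1. The dendritic cell differentiation list rose (adjusted p = 0.00898, median 0.39, 15 of 22 positive, 2 called over the list alone; adjusted p = 0.729 with an estimated correlation). Its called members were the lectin gene Mgl2 (331 and 669 CPM, log2 1.02) and the integrin gene Itgax (0.88). That list had adjusted p = 0.0957 without control 2 and 0.521 without DKO 2.

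Among lists of metabolism and repair, cholesterol and lipid handling rose (adjusted p = 0.000638, median 0.38, 18 of 24 positive, 1 called over the list alone; adjusted p = 0.729 with an estimated correlation; 0.102 without DKO 2). Mylip, which encodes a ligase that degrades the LDL receptor, was at log2 0.72 and the efflux pump gene Abcg1 at 0.43. Tissue repair and immune suppression rose (adjusted p = 0.0122, median 0.25, 20 of 27 positive, 5 called over the list alone; adjusted p = 0.729 with an estimated correlation; 0.505 without control 1 and 0.684 without DKO 2). Its members included the PD-1 ligand gene Pdcd1lg2 at log2 0.68, the elastase gene Mmp12 at 0.91 and Nt5e, which encodes the adenosine-making CD73, at -0.92. Hypoxia and glycolysis rose (adjusted p = 0.0101, median 0.09, 14 of 23 positive; adjusted p = 0.729 with an estimated correlation), with Egln3, which encodes an oxygen sensor, at 0.70 and the mitophagy gene Bnip3 at 0.56. That list was lower without control 1 (adjusted p = 0.381) and had adjusted p = 0.194 without DKO 1. Ribosomal protein genes fell (adjusted p = 4.04e-06, median -0.17, 76 of 82 negative; adjusted p = 0.729 with an estimated correlation; 0.358 without DKO 2), with Rps27 at -0.43 and Rpl35 at -0.55.

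Lists of other cells' transcripts were followed as a sign of doublets or free RNA in this class. T and NK cell transcripts rose (adjusted p = 0.00347, median log2 0.37, 16 of 18 positive; adjusted p = 0.729 with an estimated correlation; 0.0945 without control 1 and 0.0711 without doublet removal), with the NK receptor gene Klrb1c at 0.99 and the T cell receptor gene Trac at 0.71, and M16, a small cluster of this class, was led by such genes. Neutrophil transcripts fell (adjusted p = 0.00422, median -0.58, 8 of 13 negative; adjusted p = 0.729 with an estimated correlation; 0.728 without control 2), with the calprotectin gene S100a8 at -2.69 and the histamine synthesis gene Hdc at -0.71.

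The retinoic acid response list had no call (adjusted p = 0.376, median log2 -0.10, 9 of 14 negative), with the transglutaminase gene Tgm2 at 0.41 and Dhrs3 at -0.18. Macrophage identity had adjusted p = 0.908 (median 0.03, mean -0.01, tested lower), with the complement gene C1qc at 0.39, the scavenger receptor gene Stab1 at -0.48 and the folate receptor gene Folr2 at -0.64. The adjusted p was 0.107 for MHC class I presentation, 0.189 for costimulation (2 called over the list alone, Cd40 at 0.39 and Cd83 at 0.69), 0.438 for type I interferon response, 0.16 for cell cycle, 0.456 for mitochondrial transcripts and 0.124 for dissociation stress. Cell cycle passed without doublet removal (adjusted p = 0.00592), and dissociation stress passed without control 2 (0.000339) and without DKO 1 (0.00514). Cell cycle and the type I interferon response passed without each library in turn, but in opposite directions. Inflammatory cytokines and chemokines had 0.919 (median 0.04, mean -0.12, tested lower, 2 called over the list alone, Il1a and Tnfaip3). B cell transcripts had 0.194, and tumour and fibroblast transcripts 0.645 (median 0.02, mean 0.08, tested lower, 3 called over the list alone, Prrx1, Timp3 and Sparc). Of 21 lists, 10 passed with camera and 0 with fry or with an estimated correlation.

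**Figure D2:**
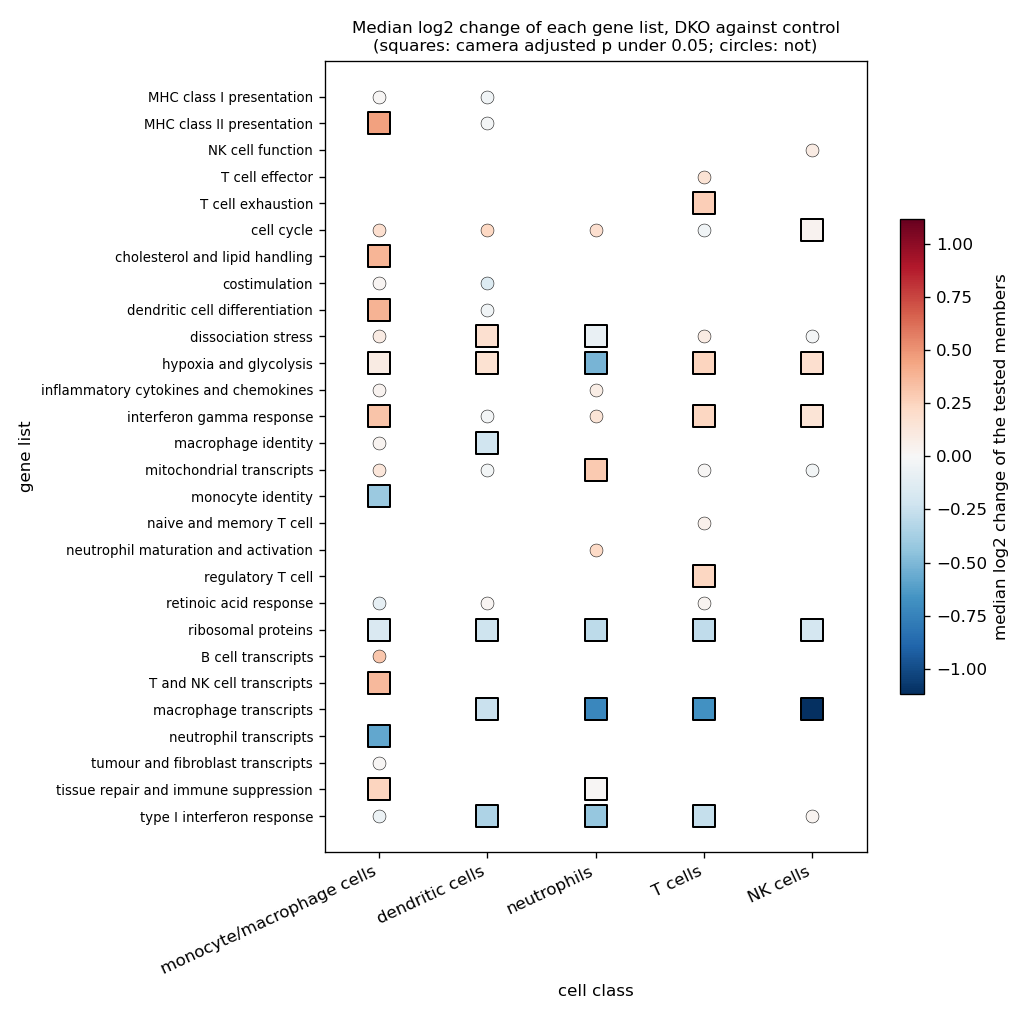
Median log2 change of each gene list in each cell class, with the lists that passed camera at the preset correlation marked.

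To assess whether states within the class differed in number, its cells were clustered again on their own. Cluster M0, led by the platelet factor 4 gene Pf4 and by Mmp9 and Ccl7, held 12.3% (11.4 to 13.3) and 28.2% (27.0 to 29.5) of the class in control and 7.71% (6.83 to 8.66) and 7.44% (6.43 to 8.55) in DKO (log2 -1.42 ± 0.70, adjusted p = 0.282; -0.70 without control 2). Cluster M3, led by Adamdec1, Tlr12, Apol7c and Igf1, held 7.93% (7.21 to 8.71) and 1.92% (1.56 to 2.33) in control and 9.96% (8.97 to 11.0) and 20.1% (18.6 to 21.8) in DKO (log2 1.61 ± 0.70, adjusted p = 0.282; 2.97 without control 1, 0.92 without control 2 and 1.02 without DKO 2). Cluster M11 (Apol7c, Cxcl9, Dnase1l3) held 2.18 ± 0.501% in control and 4.88 ± 2.66% in DKO (log2 1.16, adjusted p = 0.450; 0.46 without DKO 1), and cluster M1 (Ocstamp, Cdh1) held 16.6 ± 2.63% and 10.4 ± 0.631% (log2 -0.67). Cluster M14, led by Mt2, Adm and Egln3, held 1.5 ± 0.567% and 2.78 ± 0.490% (log2 0.89; 0.54 without control 1 and 1.33 without control 2), and cluster M15, led by Retnla and Lpl, held 1.11 ± 0.00983% and 3.18 ± 3.41% (DKO 2 alone 5.59% (4.71 to 6.58); log2 1.51; 2.33 without DKO 1 and -0.52 without DKO 2). By edgeR 0 of 17 clusters changed, 3 had an unadjusted p below 0.05, limma on log ratios called 0, and a Leiden resolution of 2.0 gave 2 calls. Groups did not overlap for 8 of 17 clusters (33.3% by chance), among them M16, 30 cells led by the T and NK cell genes Gzma and Nkg7.

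**Figure D3:**
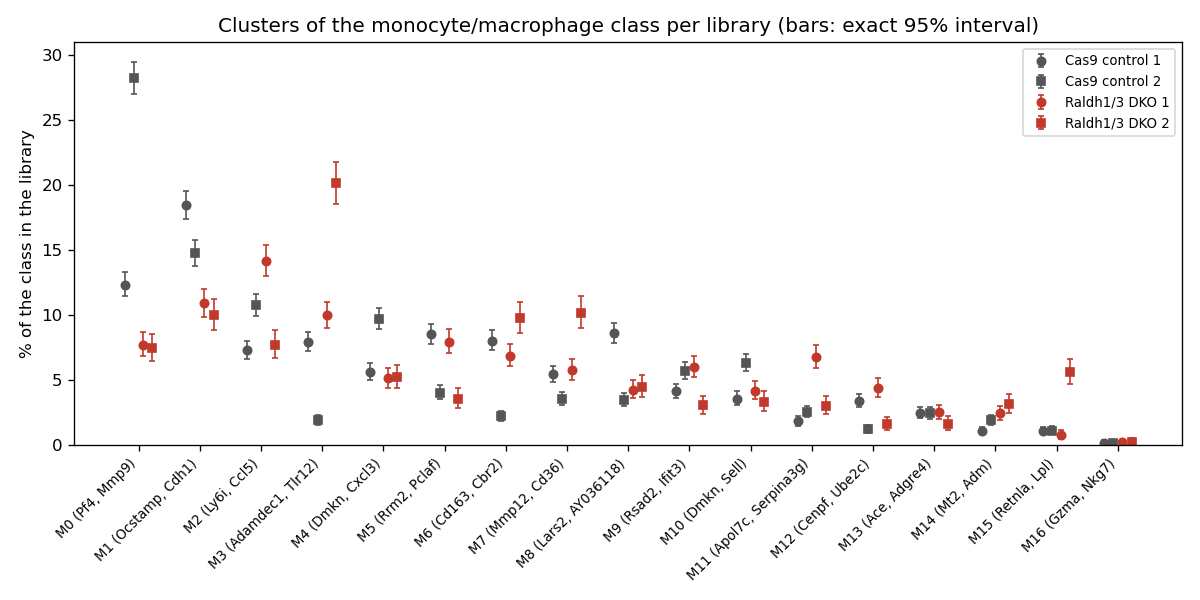
Share of each cluster within the monocyte/macrophage-like cells in each library.

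To assess dendritic-like cells, 9730 genes were tested. The adhesion gene Cadm1 and the integrin gene Itgae, which mark cross-presenting dendritic cells, were at log2 2.00 and 1.24, the stress factor gene Atf5 at 1.43, the lysozyme gene Lyz2 at -1.06, the lipid carrier gene Apoe at -0.95, the sterol synthesis gene Fdps at -1.05 and the chemokine gene Ccl17 at -1.02. Aldh1a2 was at 0.24 (-0.12 without control 2, -0.21 without DKO 2), Irf4 at 0.09 and Dhrs3 at -0.41. By edgeR 0 genes changed (smallest adjusted p = 0.116), 845 had an unadjusted p below 0.05 and DESeq2 called 17. The number of genes called by edgeR depended on which library was left out, as given in the section on processing. For 41.2% of genes the groups did not overlap (33.3% by chance).

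Of 14 lists in dendritic-like cells 6 passed camera. Ribosomal protein genes fell (adjusted p = 4.83e-12, median -0.23, 78 of 81 negative, Rpl35 at -0.63; adjusted p = 0.666 with an estimated correlation). The type I interferon response fell (adjusted p = 0.000102, median -0.34, 19 of 25 negative; adjusted p = 0.666 with an estimated correlation), with the tethering factor gene Bst2 at -0.53 and the antiviral gene Rsad2 at -0.67, but was higher without DKO 2 (adjusted p = 0.536). Hypoxia and glycolysis rose (adjusted p = 0.000102, median 0.17, 19 of 22 positive, 5 called over the list alone; adjusted p = 0.666 with an estimated correlation; 0.395 without control 1), with the angiogenic factor gene Vegfa at 1.17 and the oxidoreductase gene Ero1l at 0.78. Dissociation stress rose (adjusted p = 0.00138, median 0.18, 19 of 25 positive, 1 called over the list alone, Nr4a1 at 0.72; adjusted p = 0.455 with an estimated correlation; 0.0512 without control 1 and 0.119 without DKO 2). Macrophage identity fell (adjusted p = 0.000342, median -0.22, 14 of 20 negative, 1 called over the list alone; adjusted p = 0.455 with an estimated correlation), with Stab1 at -1.44, and had adjusted p = 0.168 at a Leiden resolution of 2.0. Macrophage transcripts fell (adjusted p = 0.000102, median -0.25, 12 of 17 negative, 4 called over the list alone; adjusted p = 0.455 with an estimated correlation), with the protease gene Ctsd at -0.66.

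In these cells adjusted p was 0.367 for dendritic cell differentiation (1 called over the list alone, Ccl17), 0.240 for costimulation (median log2 -0.16) and 0.177 for cell cycle (0.23). It was 0.973 for the retinoic acid response (median 0.02, mean 0.06, tested lower), MHC class II presentation (median -0.03, mean 0.02, tested higher), MHC class I presentation (-0.04), the interferon gamma response (median -0.02, mean 0.01) and mitochondrial transcripts (-0.03). With fry 0 lists passed.

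To assess neutrophil-like cells, 3521 genes were tested. The acute-phase gene Saa3 (chr7:46711998-46715700) fell from 119 ± 28.1 to 17.7 ± 6.82 CPM (log2 -2.86 ± 0.46, adjusted p = 0.0334), and Fam162a (chr16:36043761-36071594), a hypoxia-induced mitochondrial gene, fell from 301 ± 90.3 to 61.5 ± 31.3 CPM (log2 -2.21 ± 0.36, adjusted p = 0.0334). Without a call, the orphan receptor gene Nr4a3 was at log2 1.84, the GTPase-linked Tagap at 1.42 and Rnd1 at 1.59. The granule gene Mmp8 was at -1.55, the resistin-like Retnlg at -2.50 and the nitric oxide synthase gene Nos2 at -2.27. The edgeR test called 2 genes and DESeq2 1, with 305 at an unadjusted p below 0.05, and neither gene held with DESeq2 (Saa3 adjusted p = 1.00, Fam162a 0.125), thinning (0.372, 0.235) or a stricter cell filter (0.0638 for both). Without control 1, control 2, DKO 1 or DKO 2 it called 70, 9, 51 and 26 genes. No overlap between groups was seen for 39.6% of genes (33.3% by chance).

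Of 11 lists in neutrophil-like cells 7 passed camera. Macrophage transcripts fell (adjusted p = 1.01e-07, median -0.73, 14 of 16 negative, 3 called over the list alone; adjusted p = 0.145 with an estimated correlation; fry 0.0092), with Pf4 at -2.57 and the fibronectin gene Fn1 at -1.76. Ribosomal protein genes fell (adjusted p = 1.01e-07, median -0.29, 68 of 78 negative, 1 called over the list alone, Rpl10 at -1.26; adjusted p = 0.145 with an estimated correlation; fry 0.0092). Hypoxia and glycolysis fell (adjusted p = 2.05e-06, median -0.52, 18 of 21 negative, 1 called over the list alone; adjusted p = 0.571 with an estimated correlation), with the glycolysis genes Pfkfb3 at -1.12 and Tpi1 at -0.82. The type I interferon response fell (adjusted p = 2.76e-05, median -0.43, 20 of 22 negative; adjusted p = 0.571 with an estimated correlation; 0.201 without DKO 2), with the deISGylase gene Usp18 at -0.88 and Bst2 at -0.60. Tissue repair and immune suppression was tested lower (adjusted p = 0.0283, median 0.01, mean -0.21, 2 called over the list alone; adjusted p = 0.571 with an estimated correlation; 0.113 without control 1 and 0.201 without DKO 2). Dissociation stress fell (adjusted p = 0.0273, median -0.09, 4 called over the list alone; adjusted p = 0.571 with an estimated correlation; 0.201 without DKO 2), with the chaperone gene Hsp90aa1 at -1.16, and had adjusted p = 0.164 without doublet removal. Mitochondrial transcripts rose (adjusted p = 0.00900, median 0.29, 12 of 12 positive, mt-Nd3 at 0.78; adjusted p = 0.678 with an estimated correlation; 0.505 without control 2 and 0.201 without DKO 2).

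Neutrophil maturation and activation had adjusted p = 0.699 (median log2 0.22, 2 called over the list alone, Mmp8 and Retnlg), cell cycle 0.699 (0.18), inflammatory cytokines and chemokines 0.831 (median 0.09, mean -0.09, tested higher) and the interferon gamma response 0.831 (0.15, 1 called over the list alone, Nos2).

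To assess T-like cells, 11213 genes were tested. The myeloid lysozyme gene Lyz2 (chr10:117277331-117282321) fell from 119 ± 27.5 to 32.5 ± 1.57 CPM (log2 -1.87 ± 0.16, adjusted p = 0.0120; without doublet removal log2 -1.87 and adjusted p = 0.0887). Irf4, induced by T cell receptor signalling, was at 43.6 ± 1.87 and 82.9 ± 8.67 CPM (log2 0.93 ± 0.12, edgeR adjusted p = 0.0961). Leaving out each library in turn gave log2 0.80 to 1.03 for Irf4. Nr4a1, an early gene of the same signal, was at 127 and 224 CPM (log2 0.82) and Gfod1 at log2 0.76. Apoe was at -0.93 and the complement gene C1qb at -0.98, while Dhrs3 was at -0.39. The edgeR test called 1 gene and DESeq2 44, with 1592 at an unadjusted p below 0.05. Leaving out control 1, control 2, DKO 1 or DKO 2 gave 38, 1, 341 and 184 calls. The groups lay apart for 47.4% of genes (33.3% by chance).

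The T cell exhaustion list rose in DKO T-like cells (camera adjusted p = 0.000402, median log2 0.27, 12 of 18 positive, 3 called over the list alone; adjusted p = 0.416 with an estimated correlation), with the inhibitory receptor genes Lag3 at 0.84 and Ctla4 at 0.63 and the transcription factor gene Bhlhe40 at 0.62. The regulatory T cell list rose (adjusted p = 0.00375, median 0.24, 14 of 20 positive, 5 called over the list alone; adjusted p = 0.416 with an estimated correlation), with the costimulator gene Icos at 0.54. Its adjusted p was 0.0814 without control 1, 0.511 without DKO 2, 0.120 at a Leiden resolution of 2.0 and 0.325 without cluster 4. Hypoxia and glycolysis rose (adjusted p = 1.97e-05, median 0.25, 19 of 21 positive, 1 called over the list alone, Bnip3 at 0.77; adjusted p = 0.569 with an estimated correlation; 0.280 without control 1 and 0.0824 without DKO 1). The interferon gamma response rose (adjusted p = 0.0430, median 0.24, 15 of 20 positive, Gbp3 at 0.36; adjusted p = 0.454 with an estimated correlation; 0.0778 without control 1 and 0.625 without DKO 2), and had 0.649 without doublet removal and 0.0624 at a Leiden resolution of 2.0. The type I interferon response fell (adjusted p = 8.12e-05, median -0.26, 20 of 25 negative, 2 called over the list alone, Bst2 at -0.50 and Ifit3 at -0.66; adjusted p = 0.416 with an estimated correlation). Ribosomal protein genes fell (adjusted p = 5.25e-21, median -0.28, 78 of 81 negative; adjusted p = 0.416 with an estimated correlation), with Rpl10 at -0.64 and Rpl32 at -0.52. Macrophage transcripts fell (adjusted p = 3.29e-25, median -0.68, 16 of 17 negative, 13 called over the list alone and 1 over all genes; adjusted p = 0.328 with an estimated correlation).

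In T-like cells the effector list had adjusted p = 0.419 (median log2 0.17) and dissociation stress 0.0569 (0.09, 1 called over the list alone, Nr4a1). It was 0.978 for the naive and memory list (median 0.06, mean -0.00, tested higher), the retinoic acid response (median 0.03, mean -0.04, tested lower), cell cycle (median -0.04, mean -0.00, tested higher) and mitochondrial transcripts (0.01). Of 13 lists, 7 passed camera and 0 passed fry.

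To assess NK-like cells, 9302 genes were tested. The class included cluster 19 (Gzmg, Gzmf), which had Cd3e in 36.5% of cells and made up 7.82% to 26.8% of the class per library. Slc7a5 (chr8:121881150-121907694), which encodes an amino acid transporter of activated lymphocytes, rose (log2 1.84 ± 0.27, adjusted p = 0.00153), as did the heat shock gene Hspa1b (chr17:34956436-34959238; 1.74 ± 0.23, adjusted p = 0.000514), the survival kinase gene Pim2 (0.97, adjusted p = 0.0392), the chloride channel gene Clic4 (0.82, adjusted p = 0.0392) and the tetraspanin gene Tspan9 (2.09, adjusted p = 0.0262). The proliferation gene Mki67 fell (-1.20, adjusted p = 0.0274), as did the Ly49 receptor gene Klra5 (-1.24, adjusted p = 0.0430), the chaperone gene Sdf2l1 (-0.99, adjusted p = 0.0392) and Tnfsf11, which encodes RANKL (-2.11, adjusted p = 0.0274). The macrophage transcripts Lyz2 (-2.22 ± 0.19, adjusted p = 1.33e-06) and Apoe (-1.12, adjusted p = 0.00102) fell as well, and Dhrs3 was at 0.30 without a call. The edgeR quasi-likelihood test called 11 genes, 5 up and 6 down, and DESeq2 4, Hspa1b, Lyz2 and Apoe among them (Slc7a5 adjusted p = 0.0874).

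**Figure D4:**
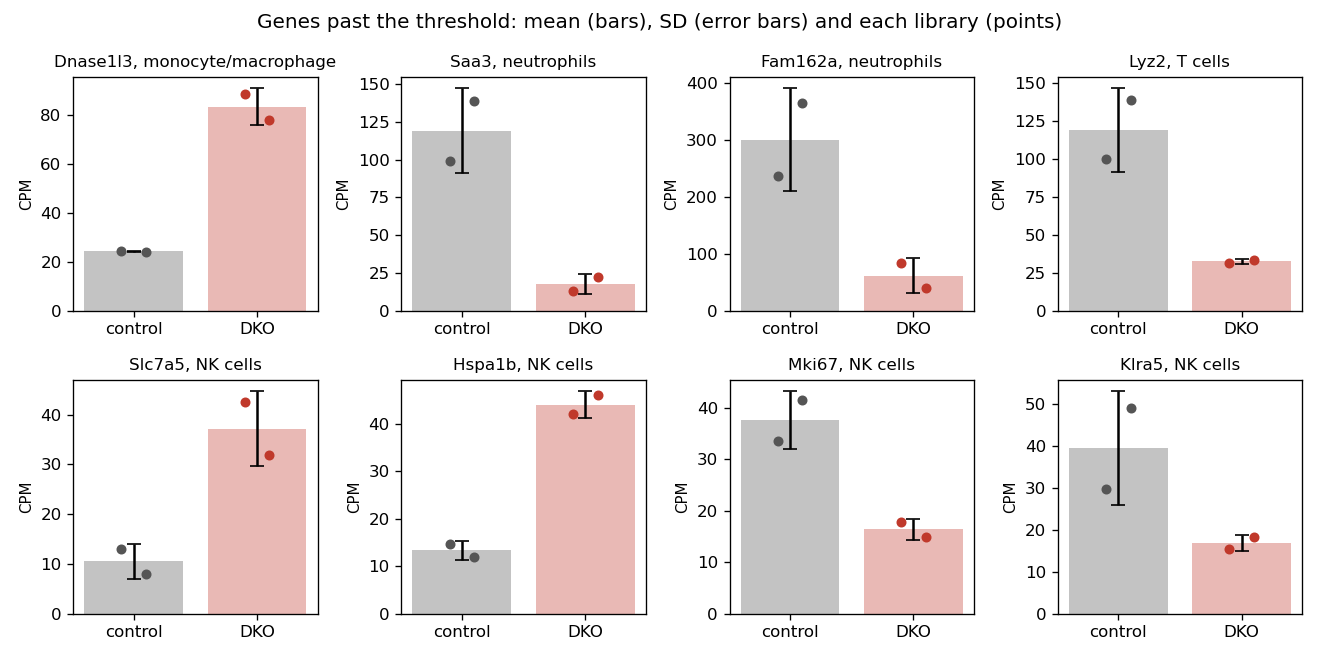
CPM in each library for a selection of the genes called in a cell class. Shown are Dnase1l3 (monocyte/macrophage-like), Saa3 and Fam162a (neutrophil-like), Lyz2 (T-like), and Slc7a5, Hspa1b, Mki67 and Klra5 (NK-like). The other genes called in NK-like cells are not drawn.

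Without DKO 2 the adjusted p in NK-like cells was 0.268 for Pim2, 0.127 for Clic4, 0.0676 for Mki67, 0.188 for Sdf2l1 and 0.0615 for Tnfsf11. Without control 2 it was 0.476 for Klra5 (log2 -0.82), 0.120 for Mki67 and 0.140 for Sdf2l1. With DESeq2 it was 0.363 for Pim2, 0.852 for Clic4, Tspan9 and Sdf2l1, 0.860 for Tnfsf11 and 1.00 for Klra5 and Mki67. With a stricter cell filter it was 0.0871 for Pim2, 0.140 for Clic4 and Tnfsf11, 0.142 for Tspan9 and Sdf2l1, 0.243 for Mki67 and 0.921 for Klra5. Pim2, Clic4, Klra5, Mki67, Sdf2l1 and Tnfsf11 also lost their calls with thinned sums (0.0825 to 0.172) and with equal cell numbers (0.105 to 0.15), and Clic4, Tspan9, Klra5 and Sdf2l1 at a Leiden resolution of 0.5 (0.0668 to 0.172). Without a cell filter it was 0.0594 for Clic4 and 0.0743 for Klra5 and Sdf2l1, and without doublet removal 0.0523 for Klra5. Hspa1b, Lyz2 and Apoe kept their calls under each alternative tried, and Slc7a5 under each apart from DESeq2. Over the class, 850 genes had an unadjusted p below 0.05, and leaving out control 1, control 2, DKO 1 or DKO 2 gave 209, 23, 108 and 28 calls. Groups did not overlap for 40.0% of genes (33.3% by chance).

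Of 9 lists in NK-like cells 5 passed camera and 0 passed fry. The cell cycle list was tested lower (adjusted p = 0.0216, median 0.04, mean -0.35, 8 called over the list alone and 1 over all genes; adjusted p = 0.463 with an estimated correlation), with the kinetochore genes Cenpf at -2.16 and Cenpe at -1.32. Hypoxia and glycolysis rose (adjusted p = 0.00108, median 0.19, 17 of 21 positive, 3 called over the list alone; adjusted p = 0.681 with an estimated correlation; 0.855 without control 1 and 0.222 without DKO 1), with Egln3 at 1.73 and Ero1l at 0.60. The interferon gamma response rose (adjusted p = 0.0230, median 0.15, 15 of 18 positive; adjusted p = 0.681 with an estimated correlation), with the GTPase gene Gbp5 at 0.49. Its adjusted p was 0.126 without control 1, 0.404 without control 2, 0.573 without DKO 1 and 0.529 without doublet removal. Ribosomal protein genes fell (adjusted p = 1.01e-05, median -0.20, 75 of 80 negative, Rpl10 at -0.47; adjusted p = 0.900 with an estimated correlation; 0.216 without control 2 and 0.555 without DKO 2). Macrophage transcripts fell (adjusted p = 9.57e-25, median -1.12, 17 of 17 negative, 11 called over the list alone and 2 over all genes; adjusted p = 0.260 with an estimated correlation), with C1qb at -0.85. The NK cell function list had adjusted p = 0.80 (median 0.09, mean -0.02, tested higher), the type I interferon response 0.910 (median 0.03, mean -0.05, tested lower), mitochondrial transcripts 0.908 (-0.03) and dissociation stress 0.80 (median -0.02, mean 0.08, tested higher, 2 called over the list alone, Hspa1b and Ier3).

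**Figure D5:**
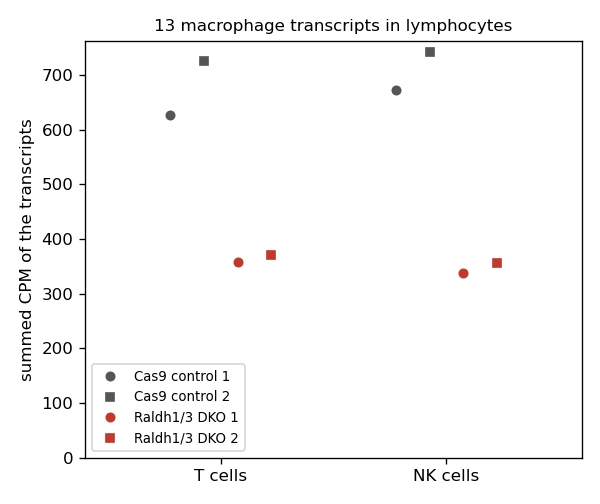
Macrophage transcripts in the T-like and NK-like cells of each library.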

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

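The comparison below was fixed before the data were examined, while the tests for free RNA and for own expression by T cells were chosen, in the form given, only after the result was seen. Values are listed here because the change between DKO and control differed between the 2 largest classes, monocyte/macrophage-like and T-like cells. Pdcd1lg2, the gene of a PD-1 ligand, was at log2 0.68 in monocyte/macrophage-like and -0.15 in T-like cells (difference 0.84), and the antigen-presentation gene H2-Aa at 0.56 and -0.22 (difference 0.77). The antigen-presentation genes H2-Ab1, H2-Eb1 and Cd74 also differed, at 0.46 and -0.30, 0.44 and -0.27, and 0.35 and -0.36. In T-like cells H2-Aa and these genes were lower, as macrophage transcripts were. Whether their T-like values come from RNA of other cells was not tested. Nt5e, the CD73 gene, was at -0.92 and 0.24 (difference -1.13), and the NK receptor gene Klrb1c at 0.99 and -0.30 (difference 1.31). Klrb1c is a member of the T and NK cell transcript list and was at 1.76 and 3.50 CPM in control and DKO monocyte/macrophage-like cells. Without doublet removal the adjusted p was 0.0515 for Nt5e, 0.0693 for Klrb1c, 0.0754 for H2-Aa and 0.159 for Lyz2, and at a Leiden resolution of 2.0 it was 0.0838 for Klrb1c. Genes made by macrophages also differed: C1qc at 0.39 and -0.45 (difference 0.85), C1qb at 0.03 and -0.98 (difference 1.02), the Fc receptor gene Fcgr4 at 0.32 and -0.77 (difference 1.10) and Lyz2 at -1.15 and -1.87 (difference 0.72). In all, 39 of 13327 genes differed (edgeR class-by-group term, adjusted p = 0.0284 for Pdcd1lg2, 0.0184 for C1qb and 0.0419 for Lyz2), and 1102 had an unadjusted p below 0.05. Of the 39, 27 were positive in monocyte/macrophage-like and negative in T-like cells, 7 the reverse, and 5 had the same direction in both classes. Without control 2, 0 genes differed, and without DKO 1 there were 3 (adjusted p for Pdcd1lg2 0.180 and 0.0946, for H2-Aa 0.220 and 0.114, for C1qb 0.120 and 0.0775, for Lyz2 0.298 and 0.223). Without control 1 there were 186, and without DKO 2 there were 58, where Nt5e had adjusted p = 0.0549, H2-Aa 0.0858, C1qc 0.0965 and Lyz2 0.125.

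Macrophage transcripts such as Lyz2, Apoe and C1qb were lower in T-like and NK-like cells of DKO. The pattern was not particular to these classes: the list had a median log2 of -0.73 in neutrophil-like (14 of 16 negative) and -0.25 in dendritic-like cells (12 of 17 negative). The values argue against doublets, since without the 10% of T-like cells richest in these transcripts the median stayed at log2 -0.613. Relative to that over all cells, the T-like median lay at log2 -0.410. As a difference of CPM values, this cannot decide on lower macrophage RNA in the whole libraries at an equal load of free RNA. T-like cells were deeper in DKO (median 5033.5 and 5977 UMIs) than in control (4789 and 4752.5), which lowers the CPM of an equal load. The median T-like cell held 6 and 7 UMIs of the list in control and 6 and 6 in DKO. Free RNA and lower expression by the T cells themselves stay open. The tests for these used the 13 members held by T-like and NK-like cells at under 5% of the monocyte/macrophage-like level. In T over NK those members had a median absolute log2 ratio of at most 0.209 in any library and a sum at log2 -0.101 at most, while the 4 members left out held 58.2%, 57.8%, 72.4% and 68.9% of the list's CPM in T-like cells of control 1, control 2, DKO 1 and DKO 2. Over all 17 members, the first form of the test, T over NK was at log2 -0.42, -0.85, -0.59 and -0.31 in these libraries, and the median absolute ratio reached 0.317. In B-like, plasmacytoid and unnamed cells the 13 members were at log2 -0.455 (0.84 without control 2) and the 17 at -0.21. An effect of the knockout stays open as untested.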

How the results depend on the processing

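The following of 5 monocyte/macrophage clusters and the fit without T cluster 4 were chosen only after the results were seen, and leaving out 1 library leaves an arm with 1 library that is assumed to vary like the others. Across the other alternatives, 63 values of class shares, 32 of cluster shares, 263 of lists and 1149 of named genes kept their direction and side of the threshold, while 5, 0, 9 and 4 reversed; 78 values of lists and 56 of genes lost a call and 3 and 116 gained one, each list or gene counting once per alternative. Leaving out 1 library kept 32, 19, 165 and 375, lost the call in 33 values of lists and 30 of genes, gained one in 1 of class shares, 24 of lists and 96 of genes, and reversed 3, 1, 50 and 7. The cause was not tested for the changes below, apart from the fewer libraries of an arm and the fewer counts after thinning or a stricter filter. Neutrophil-like cells had 1605 to 2093 UMIs per cell at the median and 83 to 347 cells per library. Over all CD45+ cells DESeq2 called 407 genes and the fit without a low-count filter 76, with 0 to 22 when leaving out 1 library (22 without control 1). Aldh1a3 was at log2 -0.14 with a stricter cell filter and -0.0767 without one, and from -0.80 (without DKO 2) to 0.95, with Aldh1a2 from -0.43 (without DKO 2) to 1.49. In monocyte/macrophage-like cells DESeq2 called 136, no low-count filter 51, thinned sums 2, a stricter cell filter 0, and leaving out 1 library 0 (DKO 2) to 243 (control 1); Aldh1a2 lay from -0.31 (without DKO 2) to 1.91 and Irf4 from -0.0902 (without DKO 2) to 1.38. Camera with an estimated correlation and fry called 0 lists there, macrophage identity had adjusted p = 0.961 at a Leiden resolution of 2.0, and the ranges of adjusted p without 1 library were retinoic acid response 0.228 to 0.671, macrophage identity 0.371 to 0.708, MHC class I 0.000237 to 0.867, type I interferon 0.000210 to 0.0168, cell cycle 3.09e-08 to 0.0394, hypoxia 1.08e-13 to 0.381, mitochondrial 0.281 to 0.728, inflammatory 0.00107 to 0.396 and tumour and fibroblast 0.00312 to 0.708. Within these ranges type I interferon was lower without control 1 (0.000237) and DKO 1 (0.000210) and higher without control 2 (0.00200) and DKO 2 (0.0168), and cell cycle was higher without control 1 (3.09e-08) and DKO 2 (7.43e-08) and lower without control 2 (0.00106) and DKO 1 (0.0394). In dendritic-like cells DESeq2 called 17 genes, no low-count filter 145, equal cell numbers 6, leaving out 1 library 0 (control 2) to 581 (DKO 1), and an estimated correlation and fry 0 lists; Dhrs3 was at 0.23 without a cell filter, Aldh1a2 from -0.21 (without DKO 2) to 0.88, and MHC class II had adjusted p = 0.992 at a resolution of 2.0. The list ranges were retinoic acid 0.497 to 0.742, MHC class II 0.111 to 0.860, MHC class I 0.0958 to 0.657, type I interferon 1.37e-17 to 0.536, interferon gamma 0.00107 to 0.812, cell cycle 2.32e-05 to 0.790 and mitochondrial 0.273 to 0.657. Here interferon gamma was lower without DKO 1 (0.0276) and higher without DKO 2 (0.00107), and cell cycle was higher without control 1 (0.000307), DKO 1 (2.32e-05) and doublet removal (0.00299) but lower without DKO 2 (0.0396). In neutrophil-like cells DESeq2 called 1 gene, no low-count filter 40, thinned sums, equal cell numbers and a stricter filter 0, no doublet removal 9, and leaving out 1 library 9 (control 2) to 70 (control 1); an estimated correlation called 0 lists, fry 2, and leaving out 1 library 4 to 9. There mt-Nd3 was at -0.0891 without a cell filter, and the ranges were maturation 5.78e-05 to 0.647, inflammatory 0.314 to 0.611 and interferon gamma 0.00629 (higher, without DKO 2) to 0.647, with 0.0423 (lower) without DKO 1. In T-like cells DESeq2 called 44 genes, no low-count filter 438, a stricter filter 5, no doublet removal 4, leaving out 1 library 1 (control 2) to 341 (DKO 1), and an estimated correlation and fry 0 lists. The cell cycle list had adjusted p = 0.976 without doublet removal, 0.0678 at a resolution of 2.0 and 0.0135 without cluster 4, retinoic acid response and mitochondrial transcripts 0.875 at a resolution of 2.0, and mitochondrial transcripts 0.853 without cluster 4. The ranges were effector 6.32e-09 to 0.398, naive and memory 0.0225 to 0.0641, retinoic acid 0.263 to 0.780, cell cycle 0.0111 to 0.316, mitochondrial 0.260 to 0.438 and dissociation 7.56e-05 to 0.994. The naive and memory list was higher without control 1 (0.0298) and DKO 1 (0.0225) and lower without control 2 (0.0349), cell cycle was lower without DKO 1 (0.0111) and higher without DKO 2 (0.0263), and the effector list was higher without control 2 (0.00925) and DKO 2 (6.32e-09). In NK-like cells DESeq2 called 4 genes, no low-count filter 124, thinned sums, equal cell numbers and a stricter filter 5, no doublet removal 27, a resolution of 0.5 7, and leaving out 1 library 23 (control 2) to 209 (control 1). An estimated correlation and fry called 0 lists, leaving out 1 library 3 to 5, with ranges of 0.555 to 0.960 for NK cell function, 0.0263 (higher, without DKO 2) to 0.855 for type I interferon (0.0498, lower, without DKO 1) and 0.555 to 0.972 for mitochondrial transcripts. Klra5 was at log2 -0.56 with a stricter filter (adjusted p = 0.921). For class shares limma on log ratios gave dendritic-like -0.22 and plasmacytoid -0.13, and a denominator without the most numerous class gave NK-like -0.0260, dendritic-like -0.24 and plasmacytoid -0.15. Leaving out 1 library called 0 to 2 classes (2 without DKO 1), with mast or basophil-like at 0.59 (without DKO 2) to 3.17, neutrophil-like at -0.92 to 0.24 (without control 2), plasmacytoid at -0.38 (without DKO 2) to 1.14 and cluster M15 at -0.52 (without DKO 2) to 2.33; a resolution of 2.0 called 2 monocyte/macrophage clusters. The difference between monocyte/macrophage-like and T-like cells was called for 16 genes without doublet removal and for 0 (control 2) to 186 (control 1) without 1 library, which need not be the same genes. The replicate numbers in the labels were also tried as a replicate block: it called 0 genes over all cells, 2 in monocyte/macrophage-like, 0 in dendritic-like, 0 in neutrophil-like, 46 in T-like and 8 in NK-like cells, 11, 6, 6, 6 and 5 lists, and 0 shares, with adjusted p = 0.958 for the cell cycle list in T-like and 0.000631 in monocyte/macrophage-like cells, 0.143 for interferon gamma in T-like cells and 0.0607 for dissociation stress in neutrophil-like cells. Libraries with the same number did not resemble each other more than others (correlation -0.172 over all cells, -0.151 in monocyte/macrophage-like, -0.198 in dendritic-like, -0.123 in neutrophil-like, -0.196 in T-like and -0.239 in NK-like cells), so the number was not used as a pair elsewhere.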

Other observations

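The shares in this part were picked, and the test for a library that stands apart was chosen, only after the results were seen; the bounds for the tests of cluster mix were written before, and their division by list came after. Cluster 22, led by the type 2 cytokine genes Il13, Il5 and Il4 and by Areg, with Cd3e in 91.8% of cells, made up 0.406% (0.276 to 0.575) and 0.243% (0.144 to 0.383) of the sorted CD45+ cells in control and 0.777% (0.573 to 1.03) and 1.57% (1.23 to 1.97) in DKO (95% Clopper-Pearson intervals; log2 1.84 ± 0.52, edgeR adjusted p = 0.144). Of its cells 42.9% came from DKO 2. Mast or basophil-like cells made up 0.183% (0.10 to 0.307) and 0.0944% (0.0380 to 0.194) in control and 0.210% (0.112 to 0.360) and 1.27% (0.968 to 1.64) in DKO, with 63.4% of them from DKO 2. Their median depth was 5369 and 1275 UMIs in control and 585 and 667 in DKO, near the lowest counts in the files. Cluster 20, led by the alternative activation gene Retnla, held 0.903% (0.662 to 1.2) and 0.806% (0.582 to 1.09) in control and 0.771% (0.504 to 1.13) and 4.89% (4.07 to 5.82) in DKO of the monocyte/macrophage-like cells, and 51.1% of its cells came from DKO 2.

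Within T-like cells, the Cd8a and Gzmk cluster 7 made up 18.9% (16.9 to 20.9) and 19.7% (17.4 to 22.2) in control and 35.3% (33.1 to 37.6) and 17.0% (15 to 19.2) in DKO, and the regulatory T cell-like cluster 14 made up 9.95 ± 0.374% and 10.6 ± 4.31% (mean ± SD). Within NK-like cells the granzyme cluster 19 (Gzmg, Gzmf), with Cd3e in 36.5% of cells, made up 7.82% (5.26 to 11.1) and 26.8% (22.5 to 31.4) in control and 19.1% (15.5 to 23.2) and 9.59% (6.77 to 13.1) in DKO. The cDC1-like cluster 29 held 2.36 ± 1.11% and 3.17 ± 2.28% of its class, a class where Cadm1 was at log2 2.00 and Itgae at 1.24 without a call. Ribosomal protein genes had a negative median in all 5 classes tested, from log2 -0.17 in monocyte/macrophage-like to -0.29 in neutrophil-like cells.

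In monocyte/macrophage-like cells the monocyte identity list was lower and the MHC class II and interferon gamma lists were higher in DKO by camera (adjusted p = 0.729 with an estimated correlation for each, and 0.698 with fry). The values argue against cluster mix as the main cause for the MHC class II and interferon gamma lists. With the same mix of clusters in each library these lists kept a share of at least 0.615 of their median. The lowest share without 1 library was 0.519 for MHC class II and 0.531 for interferon gamma. For monocyte identity cluster mix fits, since the list kept a share of 0.306. A library that stands apart fits as well: without control 2 monocyte identity kept a share of 0.392 (log2 -0.15), and without DKO 2 the MHC class II median was log2 0.24. Dendritic cells counted into the class stay open, as their other markers had a median log2 of 0.199 against 0.487 for MHC class II. An effect of the knockout on the state of these cells stays open as untested.

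In T-like cells the exhaustion and regulatory lists were higher in DKO by camera (adjusted p = 0.416 with an estimated correlation for each, and 0.351 and 0.442 with fry). Irf4 was at log2 0.98 before and 0.82 after setting the same mix of clusters. The values argue against cluster mix as the main cause for exhaustion, which kept a share of 0.653 of its median (0.652 at the lowest without 1 library). For the regulatory list mix stays open, as it kept 0.614 over all libraries but 0.361 at the lowest without 1 library. A stronger reaction to dissociation stays open, as stress genes other than the Nr4a and Egr families had a median log2 of 0.0804, and so does free RNA from other cells, as the regulatory list had a median of 0.239 in NK-like cells. An effect of the knockout on the T cells themselves stays open as untested.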
